A study of Arabidopsis thaliana with 2 samples.

How the data were processed

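Anti-HA chromatin immunoprecipitation and sequencing had been done on rosettes of a 35S:ATAF1-HA line and of wild-type Col-0, with 1 library per genotype and 10 ng of precipitated DNA each. The authors deposited 1 peak list for the series, and the submitters' processing notes name the TAIR 9 genome build. The aligner, the peak caller, its use of the wild-type library and the total reads per library are not given in the sources used here. Per the file headers, reads per peak are a count, with forward and reverse reads beside it, and they summed to the total in all 439 peaks. The deposited FDR is a percent and had no value above 4.99. The deposited strand imbalance is a fraction and equalled the absolute difference of forward and reverse reads over their sum, within 1e-06, in 438 peaks. The deposited p-value is a number between 0 and 1, and what it tests is not given in the sources used here. Since reads were not corrected for length or depth, a peak over repeated sequence can hold many reads without strong occupancy. Coordinates are those of the list, on TAIR 9, counted from 1.

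Annotation text that ran over several lines was joined (177 continuation lines). Each gene name in the list's overlap column was looked up by locus or symbol on the peak's own chromosome in a RefSeq gene table of assembly GCF_000001735.4 TAIR10.1. Of 355 distinct loci named, 353 matched. The table served for names, biotypes and gene lengths, and none of its coordinates was set against the peaks. A symbol shared by several loci took the locus whose number lay between those of neighbouring peaks. Peaks were classed as overlapping a transposable element gene, a pseudogene, a protein-coding gene, another annotated gene or no named gene. Median reads have an order-statistic 95% interval, class shares have Wilson 95% intervals and list shares exact 95% binomial intervals. No interval speaks for variation between plants.

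Peaks per chromosome were compared with the share of length in exact binomial tests (two-sided), adjusted by Benjamini-Hochberg over 5 chromosomes. With no genome sequence at hand, length was taken as the end of the last peak. A gene counted as overlapped when the overlap column named it, since transcription start sites and strands are not in the list. The 16 gene lists and 12 families (symbol patterns, at least 5 members) were fixed before the data were examined. Each was compared with the 27444 nuclear protein-coding genes in Fisher's exact test (two-sided), adjusted over the 28 together, with a threshold of 0.05. Genes were named by a rule fixed at the same time: those assigned to the 20 highest-ranked peaks, up to 4 overlapped members per list or family, and ATAF1, NCED3, TRE1, ANAC092 and GLK1 in every case. No fold enrichment is in the list, so peaks were ranked by p-value and, within ties, by reads.

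Alternatives were the 219 highest-ranked peaks alone, gene counts in place of length, protein-coding genes alone, and 10000 random lists matched on gene length. Chosen after seeing the data were the 219 peaks with the lowest FDR, removal of peaks with a p-value above 0.05, genes within 1000 or 3000 bp in the neighbour columns, genes in the hand-written notes, and removal of the NCED3 peak. Motif and 6-letter word searches need a genome sequence and were not run. Promoter classes were not run either, since the list gives no strands and coordinates of the TAIR10.1 table were not set against the peaks. No paired analysis was possible because each genotype had 1 library. The tests were checked on simulated data: among 100 random gene sets of the observed size, 1 gave a list past the threshold, and a planted list of 30 genes drawn with 20 times the weight passed in 80 of 100. For chromosomes, 2 of 100 random sets gave a call and a chromosome at double density was called in 100 of 100. Shorter planted lists, lower weights and smaller rises in density were not simulated, so power for them is unknown. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.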

Results

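ATAF1 is a NAC transcription factor of Arabidopsis thaliana, and the series mapped where its HA-tagged form sat on the genome. Chromatin was precipitated with an anti-HA antibody from rosettes of a line that expressed ATAF1-HA from the 35S promoter and from untagged wild-type Col-0 plants, the background for the antibody. Both lines were 5 weeks old and had 8 h of light per day at 21 °C. There was 1 library per genotype and no replicate, so no difference between libraries could be tested. The values come from 1 peak list of the whole series, with 439 peaks. Reads are given once per peak, without saying from which library, and the total depth of either library is unknown.

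The list held short regions spread over all 5 chromosomes. Peaks carried a median of 215 reads (order-statistic 95% interval of the median 202 to 225), with quartiles at 141.5 and 281 and a range of 78 to 6061. Median length was 40 bp, and 20 peaks reached 150 bp or more. The authors' false discovery rate (FDR) had a median of 0.948% and was under 1% in 226 peaks. Their p-value was exactly 0 in 373 peaks, between 0 and 0.05 in 42 and above 0.05 in 24.

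Which kinds of sequence lay under peaks was read from the annotation that the list gives for each peak. A protein-coding gene was overlapped by 291 of the 439 peaks (66.3%, Wilson 95% interval 61.7 to 70.6), which named 289 genes. Transposable element genes were overlapped by 51 peaks (11.6%, 8.95 to 15), pseudogenes by 8 and other annotated genes, a ribosomal RNA gene among them, by 7. The remaining 82 peaks (18.7%, 15.3 to 22.6) named no gene. Median reads were 210 in peaks on protein-coding genes, 247 on transposable element genes and 216.5 where no gene was named. Of 7 loci with 2 peaks each, 5 were protein-coding genes and 2 were transposable element genes. Among them, SIZ1 (AT5G60410), a SUMO ligase gene, held peaks of 769 reads (FDR 0.0698%, p-value 1.55e-15) and of 454 reads (FDR 4.85%, p-value 0.594), and the phospholipase D gene PLDBETA1 (AT2G42010) held peaks of 190 and 188 reads. Both genes were picked after their values were seen. Exons, introns, untranslated regions and strand are not stated in the list, so peaks inside genes were not divided further and promoters were not scored.

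**Figure D1:**
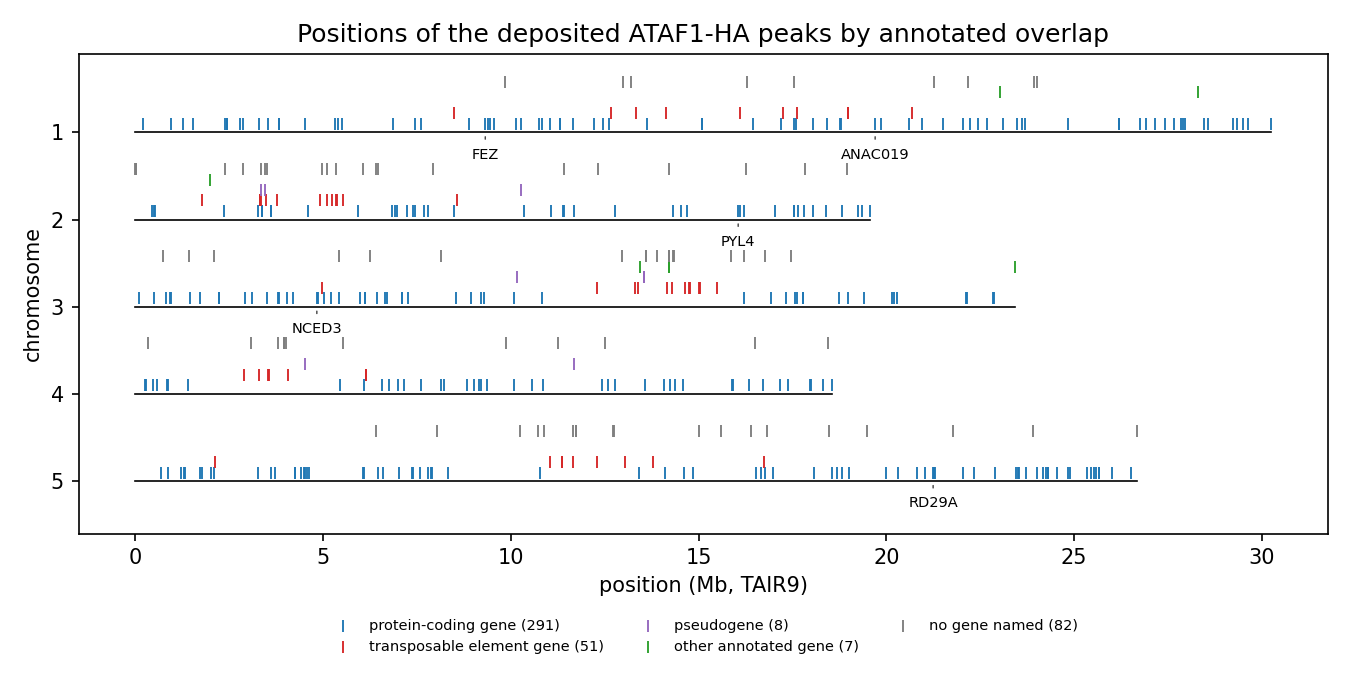
Positions of the 439 deposited peaks along the 5 chromosomes (x axis, Mb, TAIR9). Each tick is 1 peak, coloured by the annotation it overlapped; the height above each line only separates the classes, and lines end at the last peak. Chromosome 5 held the most peaks (105) and chromosome 4 the fewest (63).

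By chromosome, no departure from the share of length was called. Chromosome 1 held 99 peaks against 112 expected (ratio 0.883), chromosome 2 held 82 against 72.5 (1.13), chromosome 3 held 90 against 86.8 (1.04), chromosome 4 held 63 against 68.7 (0.916) and chromosome 5 held 105 against 98.9 (1.06). None of the 5 differed from its share in exact binomial tests (two-sided, lowest adjusted p = 0.555, lowest unadjusted p = 0.155). The share was taken from the position of the last peak on each chromosome, which stands in for chromosome length.

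The peaks that ranked highest by p-value and then by reads lay on protein-coding genes as well as on repeats. ANAC019 (AT1G52890), a stress-responsive NAC gene, ranked 3 with 612 reads and an FDR of 2.67e-05% at chromosome 1, 19697917 to 19697935. LEAFY PETIOLE (LEP, AT5G13910), which encodes an AP2/ERF transcription factor, had 420 reads at chromosome 5, 4482756 to 4482791. ABCA6 (AT3G47770), an ABC transporter gene, had 441 reads and ALDH10A9 (AT3G48170), an aldehyde dehydrogenase gene, had 434. QRT3 (AT4G20050), a polygalacturonase gene that acts in pollen separation, had 403. Peaks on the protein-coding loci AT4G01985, AT5G06800, AT5G20700, AT2G07667 and AT5G41685 carried 657, 466, 425, 414 and 412 reads. Among the same 20 peaks, AT1G37100, AT2G07784, AT5G32624 and AT5G30189 are transposable element genes (528, 472, 430 and 417 reads), AT4G07720 is a pseudogene (527) and AT1G75394 is another annotated feature (449). The other 4 named no gene and had none within 3000 bp in the list's neighbour columns. They included the first-ranked peak, at chromosome 5, 11731357 to 11731760, with 1832 reads. This ranking leaves out peaks with many reads whose p-value was above 0. Of the 20 peaks with the lowest FDR, 13 named no gene and 4 overlapped a protein-coding gene, against 10 of the 20 highest-ranked. Those without a gene included chromosome 3 from position 14201626 (6061 reads, FDR 5.24e-99%), chromosome 3 from position 13591926 (1376 reads, FDR 2.18e-124%) and chromosome 4 from position 4005968 (1226 reads, FDR 0%), each with a p-value above 0.99. Of the 4 on protein-coding genes, AT5G10340, with 2630 reads and an FDR of 0%, ranked 398 (p-value 1.03e-10), and SECA2 (AT1G21650), with 883 reads and an FDR of 5.48e-28%, ranked 395 (p-value 1.32e-12). These peaks were picked after their values were seen.

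Whether peaks lay on genes of stress, abscisic acid (ABA), senescence or carbon metabolism was asked with 16 gene lists. Peaks overlapped 4 of their 347 distinct members, against 3.65 expected (Fisher's exact test, two-sided p = 0.788). Of 7 stress NAC genes of the SNAC-A group, 1 was overlapped, ANAC019 (Fisher's exact test, unadjusted p = 0.0714). Of 16 genes of ABA synthesis and breakdown, 1 was overlapped, NCED3 (exact p = 0.156). PYL4 (AT2G38310), an ABA receptor gene, was the 1 of 33 genes of ABA perception and signalling (exact p = 0.295), with 247 reads and an FDR of 0.0394% at chromosome 2, 16050310 to 16050346. RD29A (AT5G52310), a drought- and cold-induced gene, was the 1 of 15 in the drought response list (exact p = 0.147), with 140 reads and an FDR of 1.32% at chromosome 5, 21242047 to 21242071. No list passed Fisher's exact test after adjustment (adjusted p = 1 for each), and none had an unadjusted p under 0.05.

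NCED3 (AT3G14440) encodes the 9-cis-epoxycarotenoid dioxygenase that drives drought-induced ABA synthesis. Its peak lay at chromosome 3, 4832004 to 4832025, with 199 reads, 93 forward and 106 reverse. Its deposited FDR was 2.63%, while the 4 other peaks with 199 reads all had 0.237%, as had peaks of 198 reads. An FDR near 2.63% was still found at a like read total. The peak on AT3G25290, with 197 reads, had 2.40%, and a peak of 200 reads at chromosome 5, from position 12718624, had 2.68%. Of those 200 reads 120 were forward, and 120 was the commonest count among peaks with that FDR. The NCED3 peak was the 1 peak of the list with an FDR written to 2 decimals. It was also the 1 peak whose strand imbalance, 0.07, departed by more than 1e-06 from the difference of forward and reverse reads over their sum, 0.0653. Without this peak the ABA synthesis list had 0 members overlapped.

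The other 12 lists had no member overlapped: leaf senescence (0 of 26), jasmonate (29), salicylate and immunity (19), ethylene (23), trehalose metabolism (22), carbon starvation (23), autophagy (35), photosynthesis (37), chlorophyll synthesis and chloroplast regulators (17), circadian clock (19), light signalling (12), and phenylpropanoids and flavonoids (17). Upper 95% exact binomial limits on these shares ran from 9.49% for photosynthesis to 26.5% for light signalling. Shares far above the 1.05% of all nuclear protein-coding genes were thus not excluded. At that 1.05%, the lists were expected to hold from 0.126 (light signalling) to 0.390 (photosynthesis) overlapped members each, so 0 was a likely count. The gene for ATAF1 itself (AT1G01720) was not overlapped by a peak. Neither was the trehalase gene TRE1 (AT4G24040), the senescence regulator ANAC092 (AT5G39610) or the chloroplast regulator GLK1 (AT2G20570). Overlap counts only genes named in the overlap column, and promoters were not scored, so absence of binding near these genes or lists was not shown.

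**Figure D2:**
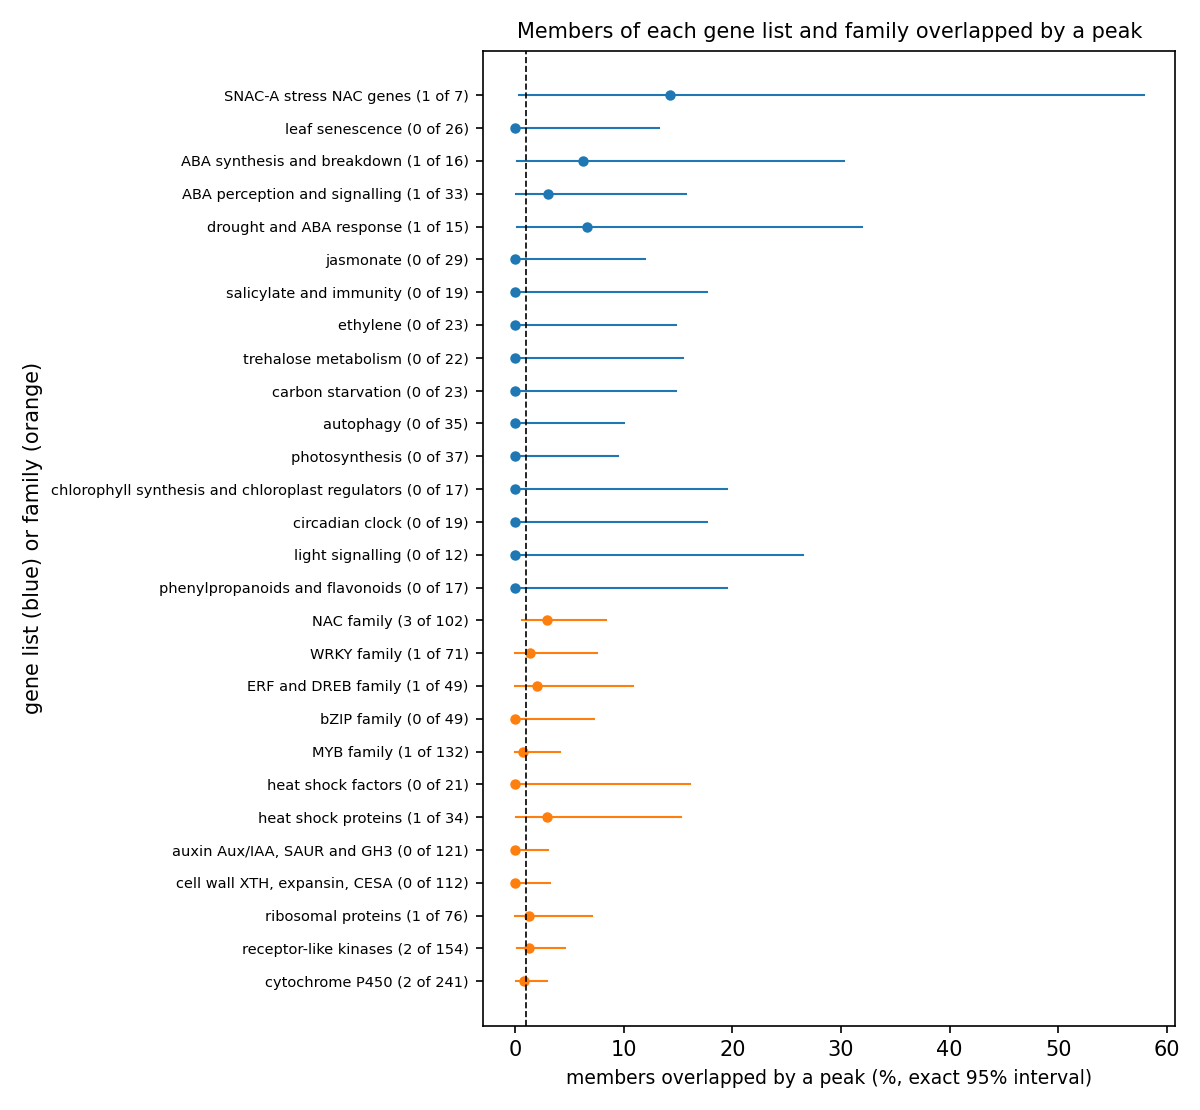
Percent of the members of each gene list (blue) and family (orange) overlapped by a peak, with exact 95% binomial intervals; the dashed line marks 1.05%, the share of all 27444 nuclear protein-coding genes. The interval of each list and family includes that line.

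A further 3 list members lay beside a peak in the neighbour columns. The trehalose-6-phosphate phosphatase gene TPPH (AT4G39770) was 252 bp from a peak of 231 reads, ANAC102 (AT5G63790) was 725 bp from a peak of 152 reads, and the autophagy gene ATG6 (AT3G61710) was 1139 bp from a peak of 368 reads. The peak beside TPPH named no overlapped gene, that beside ANAC102 overlapped SHA1 (AT5G63780) and that beside ATG6 overlapped AT3G61700. The neighbour columns are incomplete, since 316 peaks had a listed neighbour over 20000 bp away. A note added by hand to a peak of 225 reads at chromosome 5, 23899650 to 23899665, names AT5G59220 and AT5G59230. AT5G59220 is the protein phosphatase gene HAI1, a member of the senescence and ABA signalling lists, and the peak named no overlapped gene.

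Families were matched by symbol patterns and leave out members named otherwise. Among 12 such families, NAC genes had the most members overlapped, 3 of 102 against 1.07 expected (ratio 2.79, Fisher's exact test, unadjusted p = 0.0931, adjusted p = 1). Besides ANAC019 these were FEZ (AT1G26870), a regulator of root cap stem cell divisions, with 382 reads and an FDR of 0.0150%, and NTL8 (AT2G27300), a membrane-bound NAC factor, with 292 reads, an FDR of 1.24% and a p-value of 1. Receptor-like kinases had 2 of 154 overlapped, RLK902 (AT3G17840, 306 reads) and the abscission receptor HAESA (AT4G28490, 121 reads). Cytochrome P450 genes had 2 of 241, the sterol desaturase gene CYP710A2 (AT2G34490, 258 reads) and the brassinosteroid-inactivating BAS1 (AT2G26710, 185 reads). A single matched member was overlapped in each of 5 families: ERF3 (AT1G50640, 397 reads) of 49 ERF and DREB genes, the ribosomal protein gene SAG24 (AT1G66580, 313 reads) of 76, MYB116 (AT1G25340, 152 reads) of 132 MYB genes, WRKY41 (AT4G11070, 126 reads) of 71 WRKY genes and the chloroplast chaperone gene cpHsc70-1 (AT4G24280, 121 reads) of 34 heat shock protein genes. LEP and the DREB-type gene TINY2 (AT5G11590, 216 reads, picked after its value was seen) were overlapped but are not matched by the ERF and DREB pattern. No matched member was overlapped among 49 bZIP genes, 21 heat shock factors, 121 auxin genes of the Aux/IAA, SAUR and GH3 groups, or 112 cell wall genes. No family passed after adjustment over the 28 lists and families, and none had an unadjusted p under 0.05. Genes and peaks are positions in 1 list and not replicates, and the intervals cover counting error only.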

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

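The alternatives by FDR, by p-value, by neighbour columns, by notes and without NCED3 were chosen after the data were seen. The counts of chromosomes, lists and families past the threshold were 0 in the main setting and 0 under each alternative run for them. The share of peaks in a gene other than a transposable element gene was 69.7% (Wilson 95% interval 65.2 to 73.8) and ran from 65.3% to 71.2% over its alternatives. Median reads per peak were 215 and came to 256 in the 219 highest-ranked peaks and 266 in the 219 peaks with the lowest FDR. Reads break the ties of both rankings, which for the ranking score, with most p-values tied at 0, makes a higher median by construction. Without peaks with a p-value above 0.05 the median was 210. The adjusted p nearest to a call was that of the SNAC-A list (ratio 13.6, adjusted p = 1, Fisher's exact test), which was 0.0781 with neighbours within 1000 bp (ratio 24.3) and 0.0998 within 3000 bp (ratio 21.4), where ANAC102 joins ANAC019. Over its alternatives the adjusted p of the SNAC-A list ran from 0.0781 to 1. The peak beside ANAC102 overlapped another gene, SHA1. The chromosome nearest to a call was chromosome 1. Its ratio went from 0.883 to 0.733 in the 219 peaks with the lowest FDR (adjusted p = 0.09998, exact binomial test). Several ratios of observed to expected counts, none past the threshold, crossed 1. In the 219 highest-ranked peaks, chromosome 3 went to 0.993 and chromosome 4 to 1.05, and the drought response list, the WRKY family and heat shock proteins went to 0. In the 219 peaks with the lowest FDR, the ABA synthesis list, the drought response list, the WRKY family, heat shock proteins and ribosomal proteins went to 0, and without the NCED3 peak the ABA synthesis list went to 0. In each, the sole overlapped member's peak had been left out. With neighbours within 3000 bp, ribosomal proteins went to 0.987 and receptor-like kinases to 0.974, and receptor-like kinases were at 0.981 against length-matched random lists. For these and the chromosomes the cause was not tested. Planned settings on motifs and 6-letter words were not run, since they need a genome sequence. Those on promoter length, upstream assignment and overlap with a promoter were not run either. The list gives no strands, and coordinates of the TAIR10.1 table were not set against the peaks. Depth per library is unknown, and with 289 overlapped genes a list of 7 to 241 members was expected to hold 0.0737 to 2.54 of them.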

Other observations

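Regulators outside the fixed lists also lay under peaks; they were chosen after their values were seen, and no enrichment was tested for them. The paired bHLH genes of trichome fate, GL3 (AT5G41315) and EGL3 (AT1G63650), had peaks of 224 reads (FDR 0.196%) and 301 reads (FDR 0.194%), the latter with a p-value of 0.599. Peaks also lay on the FRIGIDA-pathway gene SUF4 (AT1G30970, 301 reads, FDR 1.03%), the CONSTANS-like gene COL2 (AT3G02380, 274 reads, FDR 4.85%), the histone ubiquitin ligase gene HUB2 (AT1G55250, 161 reads, FDR 4.99%), HUA1 (AT3G12680, 149 reads, FDR 0.948%) and the flowering-time gene FCA (AT4G16280, 138 reads, FDR 1.22%). The TCP factor genes TCP9 (AT2G45680) and TCP14 (AT3G47620) had 288 reads (FDR 0.283%) and 178 reads (FDR 1.60%). Others were the nitrate reductase gene NIA1 (AT1G77760, 306 reads, FDR 0.00592%), the RING ligase gene RDUF2 (AT5G59550, 330 reads, FDR 0.403%), the MAP kinase kinase gene MKK2 (AT4G29810, 203 reads, FDR 0.172%) and the dehydration-induced sugar transporter gene ERD6 (AT1G08930, 191 reads, FDR 1.59%).

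All tests in the following paragraphs were chosen after the result was seen.

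The authors' p-value was exactly 0 in 373 peaks and above 0.05 in 24, and 8 of the 20 peaks with the lowest FDR were among these 24, against 16 of the other 419 (Fisher's exact test, two-sided p = 1.92e-06). A candidate explanation is that the p-value comes from a one-sided rank-sum test of forward against reverse read positions, which would rest on the positions and numbers of reads on each strand and not on enrichment over a background. The smallest p that such a test can give under a normal approximation was computed from forward and reverse reads. This approximate limit exceeded 1e-15 in 9 peaks. Without the 2 of equal strand counts that prompted the test, the deposited value lay within 10 percent of the limit in 6 of 7. The limit is not a strict bound. At chromosome 1, from position 10754211, the deposited 6.44e-15 lay just below the rank-sum limit of 6.45e-15. In the other 430 peaks the limit was too small to inform the test. None of the 9 had a p-value above 0.05, so what sets the 24 apart remains a hypothesis. Of the 24, 19 had a p-value above 0.99. A one-sided test can give such values, but the list holds no read positions to check this. For reads of multi-copy DNA piled up on few reference positions, groups of 3 or more peaks spaced at most 20 kb held 4 of the 24 peaks and 18 of the other 415 (Fisher's exact test, two-sided p = 0.0259). The test takes peaks of the same group as independent, so its p-value may overstate the difference. Protein-coding genes held 10 of the 24 (41.7%) and 281 of the 415 (67.7%, Fisher's exact test, two-sided p = 0.0132), and median reads were 363.5 against 210, both in the direction this explanation gives. The 4 grouped peaks lay at chromosome 3, 14195988 to 14201699, and at chromosome 2, 1065 to 10087, with 2 in each group. The first group had a ribosomal RNA gene and up to 6061 reads, and the second had 743 to 1072 reads and no named gene. Pairs fall outside the rule, such as peaks among the 24 from 3951264 and from 3952837 on chromosome 4. Since 4 of the 24 lay in any such group and the list does not give copy number, this explanation stays open. Binding by ATAF1-HA stays open as well, since the list gives reads of the wild-type library apart at 0 of these peaks.

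Peaks were crowded on chromosome 2 between 3000001 and 3500000, with 12 in 500 kb against 2.1 expected. Among 10000 random placements along each chromosome, few had a bin as full (one-sided permutation p = 0.000300), which argues against even placement by chance. Reads of mitochondrial or plastid DNA placed on nuclear copies are a candidate source. Only pseudogenes were searched for annotation after organelle genes. Of 4 such pseudogene peaks in the whole list, 2 were among the 12, on AT2G07723 and AT2G07688 (Fisher's exact test, two-sided p = 0.00399). The other 10 peaks in the bin, 3 of them on protein-coding genes, were outside that search, so this source stays open. They include the peaks on AT2G07784 and AT2G07667, which ranked 8 and 17 in the list. Binding by ATAF1-HA in this region was not tested.

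Peaks lay inside protein-coding genes more often than length alone gives, 66.3% against 56.6% (exact binomial test, two-sided p = 4.05e-05), which argues against placement without regard to genes. The expected share sets gene lengths of the TAIR10.1 table against the 118 Mb spanned by peaks, and it takes no account of repeats where reads cannot be placed, which stays open. The median length of overlapped genes was 2754 bp, against 2890 bp in 1000 length-weighted draws (two-sided permutation p = 0.262) and 2078 bp over all protein-coding genes. This is consistent with genes being hit in proportion to their length, and no biological explanation was tested.

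The FDR values came in steps: 54 values were shared by at least 3 peaks each, 378 peaks in all. In 295 of these 378 the commonest count at that value was the peak's total, forward or reverse reads. That count was picked from the same peaks, so each step has at least 1 match by construction, and no chance level was computed. The steps beside the 2.63% of the NCED3 peak were 2.40% and 2.68%, with commonest counts of 121 and 120, while the NCED3 peak had 93 forward, 106 reverse and 199 total reads. Lacking the count of a step was not particular to NCED3. At 2.40%, 13 of 15 peaks held the count of 121, and AT3G25290 (64 forward, 133 reverse, 197 total) did not. The FDR of AT3G25290 was still that of a step, whereas the 2.63% of the NCED3 peak was on none of the 54 steps. The cause was not tested.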
